A study of Mus musculus with 6 samples.

How the data were processed

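RNA was sequenced from EGFP-positive dorsal root ganglion cells of 18.5 dpc mouse embryos in 6 libraries, 3 male and 3 female. Per the labels, cells from pooled ganglia were sorted with 7-AAD as a viability dye into TRIzol-LS, 10 ng of total RNA was reverse transcribed and amplified with a SMARTer ultra low input kit, and libraries were sequenced on an Illumina HiSeq instrument. The protocol amplifies full-length cDNA without molecular identifiers. Replicates were libraries of different embryos, and sex, replicate letter, number of embryos and number of ganglia were taken from the labels.

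Per the submitters' processing notes, reads were aligned with Subread, version not given in the sources used here, and assigned to genes with featureCounts 1.4.5 on GRCm38.p2. The strand and multi-mapping settings of the counting are not given in the sources used here. The authors deposited 1 file per library with raw counts per Ensembl gene, and the file headers name further columns computed from them. The deposited CPM values are the authors' counts divided by the summed counts of the same library and scaled to a common total. The deposited RPKM values are the authors' CPM divided by the summed exon length of the gene in kilobases. Both were recomputed from the counts and lengths, with a largest difference of 4.5e-11 for CPM and 1.1e-11 for RPKM against a tolerance of 1e-06. Only the counts and lengths were used from there on. Of 41388 gene identifiers, 40254 were given a symbol. The gene coordinates are those of the files. They were compared with GENCODE M21, which holds 40340 of the identifiers, 40331 of them on the same chromosome and 40281 with an overlapping span.

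Total counts ranged from 17861500 to 29330101 per library, so that 3 counts, the limit that a count of 0 allows, corresponded to 0.102 to 0.168 CPM. Mitochondrial genes took 1.10% to 2.91% of counts. Levels in the text are CPM computed with edgeR 4.0.16 and TMM factors, which ranged from 0.922 to 1.08. Mean and SD are over the 3 libraries of a sex or over 6. Ratios of the Y-linked genes carry 95% exact binomial intervals of the pooled counts, which cover counting error only.

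Female and male libraries were compared with the edgeR quasi-likelihood F-test (glmQLFit and glmQLFTest) in R 4.3.3, with TMM factors, genes kept by filterByExpr on sex, and an intercept and sex as the only terms; effects are female minus male. This left 14958 genes, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The common dispersion was 0.0966, a biological coefficient of variation of 31.1%. Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, for lists with at least 3 tested members, and adjusted over the lists. The 27 lists hold 486 different genes; Tafa4, Drgx and Ahsp carry no match by symbol in the files. Record set 2 (female B and female C) was compared with record set 1 by the same edgeR test with sex as a term. The groups, tests, filters, gene lists and the rule for named genes were fixed before the data were examined.

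Named genes were fixed by rule. They were every tested member of the Y and X lists, Ret and Gfra1 to Gfra3, up to 12 autosomal genes and 6 X genes per direction past the threshold with a mean of at least 5 CPM and no overlap between the sexes, the 4 members with the smallest p of each list past the threshold, the 2 members with the highest level of each other list, and up to 8 genes per direction between record sets. No autosomal gene, X gene or record set gene met the rule, and the rule gave 86 genes. Some genes of the lists are not reported here. Genes outside the rule are said in the text to be chosen after their values were seen. Of the 86, 9 have a near-identical copy (at least 95% identity over at least 150 bp by blastn 2.17.0, over at least 10% of the longest transcript) and 19 share at least 100 bp of exon with another gene in GENCODE M21; reads of these can be assigned differently by the unknown counting settings.

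Alternatives planned before the data were examined were RLE and upper quartile normalization, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom, robust dispersion, leaving out each library, the replicate letter as a block, record set or number of pooled embryos as a term, record set 1 only, camera with an estimated correlation, fry, females only, and plain CPM or TPM for levels. The plan named DESeq2 with its defaults; its independent filtering was instead set for the threshold of 0.05, which decides whether low-level genes such as Gm29650 receive an adjusted p. Fits without male A and male C, and record set fits without a sex term, were chosen after the data were seen. Plain library totals in place of TMM shift the median log2 change of all genes by -0.113, and changes are given relative to the TMM scale. The tests were tested on simulated data of 14664 genes with the spread of these libraries, in which edgeR made 9 false calls among 133, DESeq2 33 among 179 and limma voom 8 among 128, and camera called 1 of 26 lists, the 1 that had been shifted 2-fold. Genes were simulated independently, so this cannot show how camera behaves where list members vary together. Estimated correlations of the lists called between the sexes ran from 0.202 to 0.805. File handling and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library was left out of the comparisons. Genes failing the filter were left out of the tests, and an EGFP-negative arm was not analysed here.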

Results

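RNA was measured in sensory ganglion cells that carried a Ret-EGFP reporter, sorted from C57BL/6 mouse embryos at 18.5 dpc (days after coitum). Ret encodes the receptor tyrosine kinase through which GDNF family ligands signal, and the reporter was built to mark cells that express Ret. The series description gives EGFP as knocked into the Ret locus in heterozygotes, whereas the genotype label names a Ret-EGFP transgene, so the number of intact Ret alleles behind the Ret level is not settled here. Dorsal root ganglia (DRG) from spinal levels T11 to S1, which innervate the lower trunk, pelvis and hindlimb, were dissociated, and EGFP-positive cells were collected by flow cytometry. The 6 libraries comprised 3 from males (A, C and D) and 3 from females (A, B and C), made from different embryos. Male A and female A each held 60 ganglia of 3 embryos, male C and male D each held 40 ganglia of 2 embryos, and female B and female C each held 20 ganglia of 1 embryo. The embryos of male C, like those of female A, came from 2 mothers. Female B and female C also belong to a second set of records, described in a different form, and are called record set 2; the other 4 libraries are record set 1. Total counts per library were 17861500 in male A, 29330101 in male C, 21423641 in male D, 21734364 in female A, 19615536 in female B and 20885601 in female C. Between 19974 and 22052 genes had at least 1 count in a library. A count of 0 allows a level of up to 0.102 to 0.168 CPM (counts scaled by the library total), taken as 3 counts. These limits cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

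To establish what the sorted cells expressed, levels of fixed marker genes were computed in the 6 libraries. Levels are CPM with TMM factors, as mean ± SD with n = 6 unless stated, and the examples named from each list were chosen after their values were seen. Ret itself (ENSMUSG00000030110, GRCm38 chromosome 6, 118151748 to 118197744, minus strand) stood at 181.6 ± 27.2 CPM. Of its co-receptors, Gfra3, which binds artemin, had the highest level at 441 ± 84.0 CPM. Gfra2, the neurturin co-receptor, reached 79.96 ± 9.25 CPM and Gfra1, the GDNF co-receptor, 34.3 ± 8.32 CPM. The ligands themselves were close to undetected, with means of 0.017 CPM for Gdnf, 0.076 CPM for Nrtn and 0.019 CPM for Artn. General neuronal and sensory transcripts were abundant. Stmn2 stood at 5300 ± 791 CPM and Tubb3 at 4468 ± 1029 CPM, with Prph, the peripheral neuron intermediate filament, at 830 ± 41.6 CPM and Isl1, a sensory lineage transcription factor, at 720 ± 124 CPM. Peptidergic nociceptor transcripts were present, including Calca, which encodes CGRP, at 1572 ± 457.5 CPM, Tac1, which encodes substance P, at 439 ± 51.4 CPM. The capsaicin receptor Trpv1 was at 176 ± 31.4 CPM. Non-peptidergic transcripts stood beside them, with the receptor Mrgprd at 283 ± 77.9 CPM, Mrgprx1 at 220.4 ± 55.0 CPM. The ATP-gated channel P2rx3 was at 363 ± 99.2 CPM and the sodium channel Scn11a at 584 ± 170 CPM. The pruritogen receptor Mrgpra3 had a mean of 1.41 CPM. Of the C-fibre low-threshold mechanoreceptor (C-LTMR) genes, Fam19a4 was at 201 ± 29.2 CPM and Th, tyrosine hydroxylase, at 49.6 ± 17.8 CPM. The mechanically gated channel Piezo2 was at 472 ± 131.5 CPM. Genes of myelinated mechanoreceptors and proprioceptors spanned a wide range, with Etv1 at 182.7 ± 37.1 CPM, Nefh at 86.6 ± 35.7 CPM, Ntrk2 at 43.7 ± 9.32 CPM, Ntrk3 at 13.1 ± 3.58 CPM and Pvalb at 6.47 ± 5.00 CPM. Runx3, a proprioceptor transcription factor, had a mean of 0.495 CPM, and Mafa had no counts. RNA of non-neuronal cells was also detected, with the satellite glia gene Fabp7 at 450 ± 71.7 CPM, whereas the leukocyte gene Ptprc was at 0.353 CPM. Hox genes of thoracic and lumbosacral identity were present, with Hoxa7 at 38.4 ± 4.80 CPM and Hoxd10 at 37.2 ± 16.2 CPM, and Hoxb13, a gene of the tail region, at 0.009 CPM. CPM is not divided by gene length, so the levels of different genes do not rank their numbers of transcripts. An EGFP-negative arm was not analysed here, so these levels are not an enrichment over unsorted cells.

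**Figure D1:**
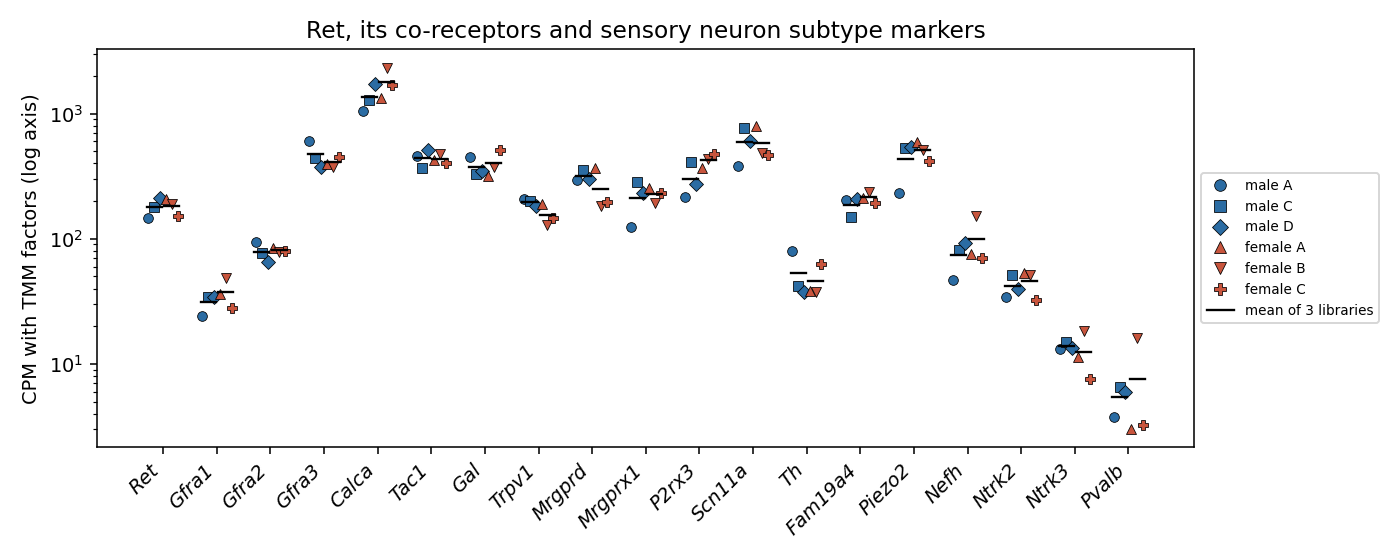
Level of Ret, its co-receptors and markers of sensory neuron classes in each library, in CPM with TMM factors on a log axis, with 1 point per library coloured by sex and a bar at the mean of the 3 libraries of each sex. Calca (mean 1572 CPM) and Gfra3 (441 CPM) lie well above Ntrk3 (13.1 CPM) and Pvalb (6.47 CPM) in CPM, which is not divided by gene length. The points of both sexes overlap for Ret.

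To determine which transcripts differed between the sexes, female libraries were compared with male libraries, beginning with the sex chromosomes. The 4 tested genes of the fixed Y-linked list were present in all 3 male libraries and close to 0 in all 3 female libraries. Kdm5d, a histone H3K4 demethylase (ENSMUSG00000056673, Y chromosome 897788 to 956786, plus strand), was at 12.3 ± 3.21 CPM in males and 0.0337 ± 0.0296 CPM in females (SD, n = 3 each). Eif2s3y, a translation initiation factor subunit (ENSMUSG00000069049, 1010543 to 1028847, plus strand), was at 42.9 ± 21.9 CPM in males and 0.238 ± 0.0884 CPM in females. Uty, a paralogue of the demethylase gene Kdm6a (ENSMUSG00000068457, 1096861 to 1245759, minus strand), was at 26.1 ± 15.95 CPM in males and 0.0856 ± 0.0349 CPM in females. Ddx3y, an RNA helicase gene (ENSMUSG00000069045, 1260771 to 1286629, minus strand), was at 102.8 ± 86.15 CPM in males and 0.293 ± 0.175 CPM in females. The male to female ratio of pooled counts per library total was 386 for Kdm5d (95% exact binomial interval 107 to 3200), 183 for Eif2s3y (109 to 335), 323 for Uty (138 to 995) and 371 for Ddx3y (232 to 637). The fitted log2 changes, female minus male, were -8.29 for Kdm5d, -7.48 for Eif2s3y and -8.19 for Uty, each with adjusted p = 0.00163, and -8.46 for Ddx3y with adjusted p = 0.00607. Of 7 Y genes tested, 4 were called. Gm29650, a non-coding RNA gene named after its values were seen, was at 0.853 ± 0.557 CPM in males with no female counts and was called by DESeq2 and without a low-count filter. The testis-determining gene Sry and Zfy1 and Zfy2 had no counts in the 6 libraries, and Usp9y and Uba1y had 1 count each. No gene passed the threshold without female A, where all 4 Y genes had adjusted p = 0.0727, or with record set as a term, where their adjusted p ranged from 0.467 to 0.801. The same held in record set 1 only (adjusted p from 0.824 to 1), and limma voom called Kdm5d alone. The log2 changes of the 4 genes ran from -8.58 to -7.19 without female A and from -10.05 to -7.90 with record set as a term. Ddx3y was not called without female B (adjusted p = 0.0802) or without female C (adjusted p = 0.0775).

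Xist, the non-coding RNA that coats and silences the inactive X chromosome (ENSMUSG00000086503, X chromosome 103460375 to 103483217, minus strand), averaged 146.6 CPM in females, with libraries between 111.5 and 197.4 CPM, and 19.97 ± 33.7 CPM in males (SD, n = 3). The male libraries were unlike one another, with 0.418 CPM in male A and 0.576 CPM in male D but 58.9 CPM in the library labelled male C, which held 1860 Xist counts. Xist did not pass the threshold over the 6 libraries, with a log2 change of 2.86 and a standard error of 1.38 (adjusted p = 0.961). Without male C the log2 change was 8.18 and Xist was called (adjusted p = 0.000665), as it was with the replicate letter as a block (log2 change 4.42, adjusted p = 1.68e-07). It was also called without both male A and male C, chosen after the data were seen (log2 change 7.97, adjusted p = 3.84e-05), and over the other settings run its adjusted p lay between 0.305 and 1. Exons of Xist overlap those of its antisense partner Tsix over 1980 bp, and the strand setting of the read counting is not given in the sources used here. No gene reported to escape X inactivation passed the threshold gene by gene. Kdm5c, the X paralogue of Kdm5d, was at 61.5 ± 7.78 CPM in females and 40.4 ± 4.08 CPM in males (log2 change 0.61, adjusted p = 0.961), with each female library above each male library. Kdm6a was at 35.3 ± 7.04 CPM in females and 25.2 ± 11.6 CPM in males, with a log2 change of 0.48. Eif2s3x had a log2 change of 0.42, with 37.0% of its transcript found in a near-identical copy in another gene, and Ddx3x one of 0.17. Of the remaining tested genes, 5530601H04Rik (0.35), Ftx (0.30), Pbdc1 (0.22), Jpx (0.12), Shroom4 (0.11), Utp14a (0.11) and Syap1 (0.02) had positive log2 changes and Usp9x (-0.12) and Uba1 (-0.14) negative ones. As a group, the X inactivation centre and escape list rose in females, with 12 of 14 tested members higher (adjusted p = 0.0179). The call was lost with adjusted p = 0.7 with an estimated correlation, and it was also lost without male A (adjusted p = 0.577), in which this list was lower than in every other library, and without female A (adjusted p = 0.242). Adjusted over the list alone, 0 of 14 X genes and 4 of 4 Y genes were called. The Y-linked list fell in females (4 of 4 lower, adjusted p = 1.49e-22; adjusted p = 0.0998 with an estimated correlation).

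**Figure D2:**
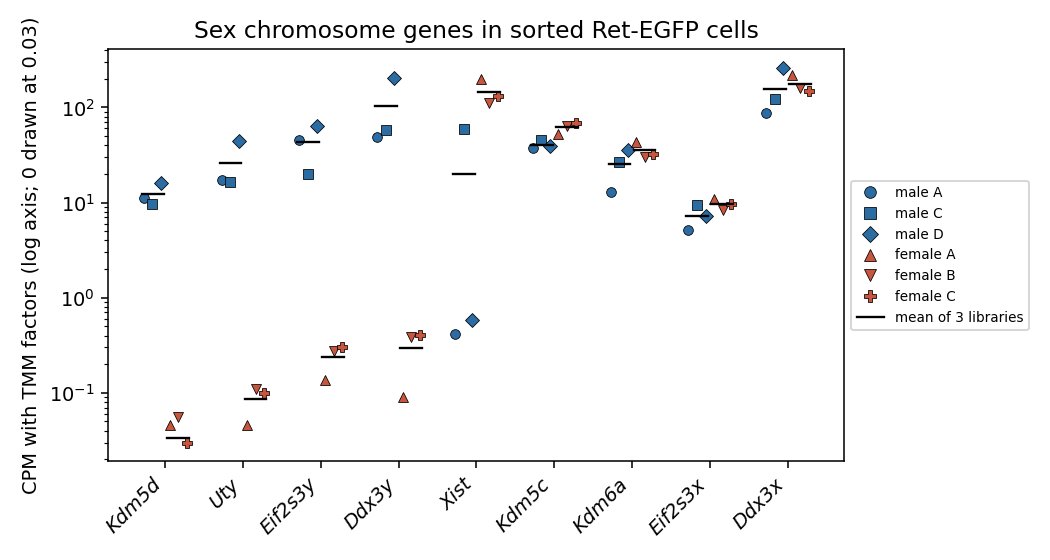
Level of 4 Y-linked genes, Xist and 4 X-linked genes in each library, in CPM with TMM factors on a log axis, with a level of 0 drawn at 0.03, 1 point per library and a bar at the mean of the 3 libraries of each sex. The Y-linked genes stay at or below 0.401 CPM in every female library, and the library labelled male C holds 58.9 CPM of Xist against 0.418 and 0.576 CPM in the other 2 male libraries.

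Outside the sex chromosomes no gene passed the threshold between the sexes. The male libraries included male C, with Xist at 40.2% of the female mean, and any female RNA in it would reduce the differences. Without male C edgeR also called 0 autosomal genes. The edgeR test called 0 of 14378 autosomal genes, with 639 at an unadjusted p under 0.05 (421 higher and 218 lower in females), and the smallest adjusted p among autosomal genes was 0.961. Of the autosomal genes, 8.02% had all 3 libraries of a sex above all 3 of the other, where chance gives 10%. Of 552 X genes, 0 were called and 16 had an unadjusted p under 0.05, 12 of them higher in females, and 8.33% did not overlap between the sexes. Over all 14958 tested genes the calls were the 4 Y genes, with 661 genes at an unadjusted p under 0.05. Limma voom called 0 autosomal genes, and DESeq2 called 8. The 8 genes, named after their values were seen, were Skil, Rbm15, Gm12940, Spry2, Tob1, Kif26a and Wtap, higher in females, and Pmp2, lower. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, was at 91.6, 556.2 and 259.8 CPM in females A, B and C and at 25.6 to 77.5 CPM in males. Wtap, a subunit of the RNA m6A methylation complex, was at 80.2, 239.1 and 228.3 CPM in females A, B and C and at 27.3 to 69.0 CPM in males. In both genes the highest levels were those of female B and female C, the libraries of record set 2. The peripheral myelin gene Pmp2 was at 16.7 CPM in male A and at 0.25 to 1.77 CPM in the other 5 libraries. Without a low-count filter edgeR called 8 autosomal genes among 25811 genes tested. Without male D it called Snhg14, the host transcript of imprinted small nucleolar RNAs (adjusted p = 0.0316). Snhg14, also named after its values were seen, was at 38.4 and 42.7 CPM in male A and male C and at 149.9 to 190.7 CPM in the other 4 libraries. With the replicate letter as a block, which leaves 1 residual degree of freedom, edgeR called 65 autosomal genes. In simulated data of this design edgeR recovered 15.4% of genes changed 2-fold, 76.1% of genes changed 4-fold and 96.9% of genes changed 8-fold. The simulation changed 65 to 67 genes at each fold, drew genes independently and held no library that stood apart. More changed genes ease the adjusted threshold, so these shares may overstate the recovery in the real libraries.

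To determine whether genes of a cell type or pathway moved together between the sexes, 27 lists fixed before the data were examined were tested as groups. Of these, 26 had at least 3 tested members and 10 passed the threshold, including the Y and X lists. In each of the 5 lists below that fell in females the mean level was highest in male A. Each of the 8 calls below had adjusted p = 0.7 with an estimated correlation, and adjusted over the list alone 0 of their members were called. Endothelial and pericyte markers fell in females (10 of 10 lower, adjusted p = 1.49e-05). The junction protein gene Esam was at 8.89 CPM in male A and 0.351 to 1.49 CPM elsewhere, and the angiopoietin receptor gene Tek had a log2 change of -1.55, Emcn of -1.48 and the VEGF receptor gene Kdr of -1.22. This was the only list of another cell type still called without male A (adjusted p = 0.0066), and it was not called without both male A and male C, an alternative chosen after the data were seen (adjusted p = 0.0969). Cell cycle genes fell (18 of 19 lower, adjusted p = 0.00123), with the replication gene Mcm6 at 94.4 CPM in male A and 28.5 to 64.6 CPM elsewhere and Mcm3 at 37.6 against 4.75 to 9.66 CPM. The proliferation marker Mki67 had a log2 change of -1.32 and Mcm5 of -0.99. Fibroblast and meningeal markers fell (11 of 13 lower, adjusted p = 0.00695), with the collagen genes Col3a1 at 847.8 CPM in male A and 32.3 to 72.1 CPM elsewhere and Col1a2 at 771.2 against 85.0 to 109.5 CPM. The matricellular gene Postn was at 207.1 against 53.0 to 109.8 CPM and Lum had a log2 change of -1.10. Satellite glia and Schwann cell markers fell (13 of 16 lower, adjusted p = 0.0316), with the glial transcription factor gene Sox10 at 43.7 CPM in male A and 6.76 to 10.3 CPM elsewhere and the myelin enzyme gene Cnp at 399 against 68.5 to 85.1 CPM. The lipoprotein gene Apoe was at 964.9 against 137 to 342 CPM and Egfl8 at 55.3 against 3.55 to 6.21 CPM. Macrophage and immune markers, of which 3 of 13 were tested, fell (3 of 3 lower, adjusted p = 0.0179). Lyz2 was at 1.36 CPM and the complement gene C1qb at 1.88 CPM in male A, with log2 changes of -1.29 and -1.34, and Fcer1g had -0.35. Pan-sensory neuron genes rose in females (14 of 16 higher, adjusted p = 0.0226), and their mean level was lowest in male A. It was highest in females B and C of record set 2, while female A (mean log2 CPM 8.92) lay below male D (9.05). The sensory transcription factor gene Pou4f1 was at 1251 ± 294 CPM in females and 614.5 ± 211 CPM in males (SD, n = 3 each, log2 change 1.03, standard error 0.28, adjusted p = 0.961). Each female library was above each male library, but female A (914.5 CPM) was close to male D (857.7 CPM), with 1460 and 1378 CPM in females B and C. Prdm12, needed for nociceptor formation, had a log2 change of 0.69, the neurofilament gene Nefl 0.30 and Isl1 0.29. Erythroid markers rose (6 of 6 higher, adjusted p = 0.0226), with log2 changes of 0.94 for the carbonic anhydrase gene Car2, 0.84 for the haem synthesis gene Alas2, 0.67 for Hba-a1 and 0.45 for Hba-a2, and male A and male C had the lowest levels. Mitochondrially encoded mRNAs rose (6 of 7 higher, adjusted p = 0.0308), with log2 changes of 0.69 for mt-Co1, 0.40 for mt-Nd1, 0.28 for mt-Nd5 and 0.25 for mt-Cytb, and male A and male C again had the lowest levels. Near-identical copies in other genes cover 76.97% of the Hba-a1 transcript, 97.11% of Hba-a2, 100% of mt-Co1 and 52.3% of mt-Nd5. Their log2 changes may therefore not be specific to the gene. Every member named here had adjusted p of at least 0.961.

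Without male A the calls for glia (adjusted p = 0.941, direction up), fibroblasts (0.974, up), cell cycle genes (0.577, up), macrophages (0.604), pan-sensory genes (0.323), erythroid markers (0.323) and mitochondrial mRNAs (0.604) were lost. Single libraries of the other 5 also ended some of these calls. The glia list was not called without female A (adjusted p = 0.191) or female C (0.0772), the macrophage list without male D (0.938) or female C (0.0772), the pan-sensory list without male C (0.0697), female B (0.0875) or female C (0.0855), and the erythroid list without male C (0.224), female A (0.252) or female C (0.0684). The mitochondrial list was not called without male C (adjusted p = 0.256), female A (0.18) or female C (0.0855), and without both male A and male C it fell in females (adjusted p = 0.0087). With record set as a term, where female A alone stands for the females, the fibroblast, glia, pan-sensory and mitochondrial lists were not called. With the replicate letter as a block neither the pan-sensory (adjusted p = 0.111) nor the macrophage list (0.0986) was called.

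**Figure D3:**
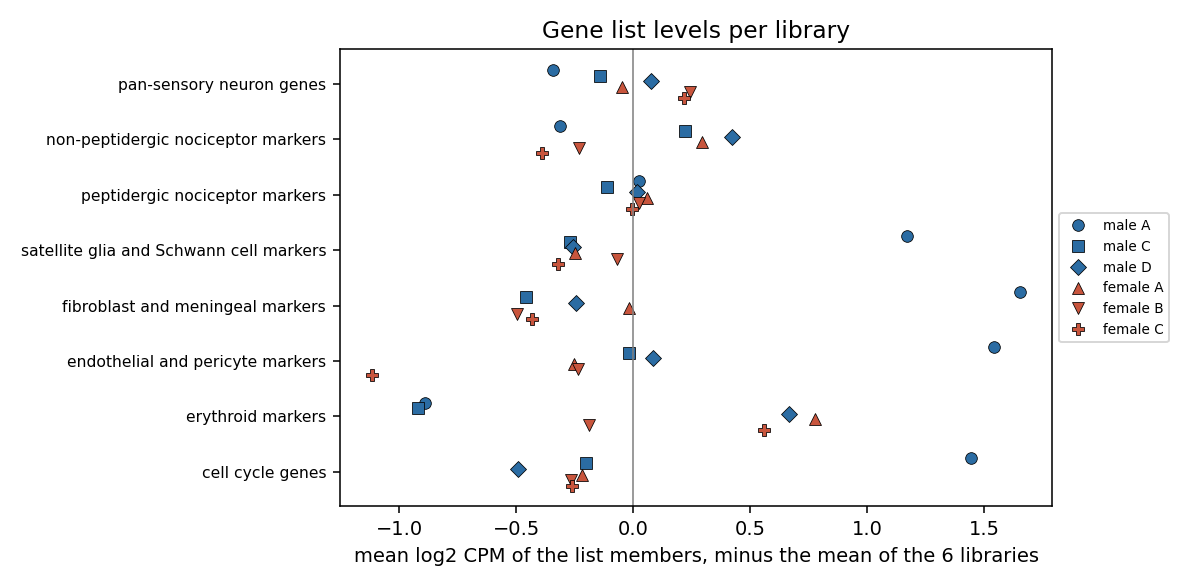
Mean log2 CPM of the tested members of 8 gene lists in each library, each list centred on its mean over the 6 libraries, with 1 point per library. Male A stands apart from the other 5 libraries for satellite glia (6.91 against 5.42 to 5.67 before centring), fibroblast (5.95 against 3.80 to 4.28) and cell cycle genes (4.87 against 2.93 to 3.22).

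The genes of Ret signalling and of the sensory neuron classes did not pass as groups between the sexes. Of GDNF family ligands, receptors and targets, 6 of 12 were higher in females (adjusted p = 0.522; median log2 change -0.02, mean 0.19, test direction up); adjusted over the list alone Spry2 was called, 1 of 12. Ret differed by 0.04 on the log2 scale, with a standard error of 0.21 and adjusted p = 0.996, from 179.3 ± 31.4 CPM in males to 183.9 ± 29.0 CPM in females (SD, n = 3 each). Gfra1 (0.28), Gfra2 (0.04), Gfra3 (-0.21) and the Ret adaptor gene Dok4 (-0.22) had small log2 changes. Non-peptidergic nociceptor markers were lower in females in 10 of 13 cases (adjusted p = 0.208), with P2rx3 at 0.50 and Scn11a at -0.02 on the log2 scale. This list fell in females without male A (adjusted p = 0.0066), without female A (adjusted p = 0.0302) and, chosen after the data were seen, without male A and male C (adjusted p = 0.0282). It was not called in any other setting, with adjusted p = 0.7 with an estimated correlation (0.302) and direction up with record set as a term (adjusted p = 0.267). Its levels were lowest in female C, male A and female B. Peptidergic nociceptor markers were divided evenly, with 6 of 12 higher (adjusted p = 0.887; median 0.03 and mean 0.01 with test direction down), Calca at 0.40 and Tac1 at -0.03. C-LTMR markers had 4 of 7 higher (adjusted p = 0.447), with Piezo2 at 0.22 and Fam19a4 at 0.20, and myelinated mechanoreceptor and proprioceptor markers 9 of 14 (adjusted p = 0.447), with Nefh at 0.44 and the transcription factor gene Etv1 at 0.13. Synaptic vesicle genes had 13 of 20 higher (adjusted p = 0.432), with Syt4 at 0.68 and Snap25 at 0.60. Sensory ion channels had 12 of 24 higher (adjusted p = 0.887; median 0.04, mean below 0, test direction down), with the nociceptor sodium channel genes Scn9a at 0.22 and Scn10a at 0.10. Neurotrophin and growth factor receptors had 6 of 13 higher (adjusted p = 0.824; median -0.07, mean 0.05, test direction up), with Lifr at 0.33. Adjusted over the list alone 0 members of these lists other than Spry2 were called.

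Among the remaining lists, steroid hormone receptors and enzymes had 9 of 13 higher in females (adjusted p = 0.234), with Hsd17b12 at 0.21 and Hsd17b4 at -0.20 on the log2 scale. Axon guidance genes had 17 of 22 higher (adjusted p = 0.0858), with the ephrin gene Efna5 at 1.09 and the semaphorin receptor gene Nrp1 at 0.35, and they were called only with the replicate letter as a block (adjusted p = 0.0422; 0.7 with an estimated correlation), with direction down without male A and male C (0.756). Posterior Hox genes had 10 of 13 higher (adjusted p = 0.208), with Hoxa7 at 0.15 and Hoxd10 at 0.02, and were called only without female A (adjusted p = 0.0303), which leaves females B and C of record set 2. With record set as a term (adjusted p = 0.138) and without male A and male C (0.578) the direction was down, and with an estimated correlation (0.415) adjusted p was 0.7. Cytosolic ribosomal protein genes were lower in 46 of 61 cases (adjusted p = 0.0858), with Rpl4 at -0.15 and Rps3 at -0.03. They fell in females without male C (adjusted p = 0.0133), male D (0.0334), female B (0.0206) or female C (0.0155). They were not called with an estimated correlation (0.349, adjusted p = 0.747) or without female A (adjusted p = 0.967), and without male A the direction was up (adjusted p = 0.941). With record set as a term the direction was down, but that fit sets female A alone against the males. The mean log2 CPM of this list was lowest in female A (4.92), with 5.17 and 5.20 in females B and C and 4.99 to 5.44 in the males. Nuclear-encoded oxidative phosphorylation genes were lower in 24 of 37 cases (adjusted p = 0.148), with Cox4i1 at -0.21 and Ndufa4 at 0.14. They fell without female B (adjusted p = 0.02), but not with an estimated correlation (adjusted p = 0.7). With record set as a term the direction was down, again with female A alone for the females. Female A had the lowest mean log2 CPM of this list (7.31, against 7.39 to 7.59 elsewhere). Immediate early and dissociation stress genes had 14 of 27 higher (adjusted p = 0.447; median 0.22, mean -0.06, test direction up), with Fos at 0.63 and the chaperone gene Hspa8 at -0.23, and rose without male A (adjusted p = 0.00828), in which their mean level was the highest. They were not called with an estimated correlation (0.328; adjusted p = 0.888) or without male A and male C (adjusted p = 0.578), and the direction was down with record set as a term (adjusted p = 0.138). Spinal cord neuron markers had 3 of 3 tested genes higher (adjusted p = 0.447), with the choline transporter gene Slc5a7 at 0.33 and Hoxc9 at 0.05. Sympathetic and enteric neuron markers were lower in 6 of 7 cases (adjusted p = 0.913; median -0.47, mean -0.52, test direction up), with the monoamine transporter gene Slc18a2 at 1.05 and Chrna3 at -0.01. Of 12 skeletal muscle markers 2 were tested, too few for a test as a group, with Acta1 at 9.85 ± 2.30 CPM and Mylpf at 2.10 ± 0.496 CPM (SD, n = 6). Adjusted over the list alone, 0 members of these lists were called. Every gene named for these lists that did not pass as a group had an adjusted p above 0.05.

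Female B and female C differ from the other libraries in record set and in pool size, so record set 2 was compared with record set 1. The genes named here come from the fit without male A and without a sex term, an alternative chosen after the data were seen, and were themselves chosen after their values were seen. Cox5a, a cytochrome c oxidase subunit gene, was at 17.3 and 10.97 CPM in female B and female C and at 95.1 to 165.5 CPM in the other 4 libraries (log2 change -3.12, standard error 0.27, adjusted p = 0.0128). Cyc1, which encodes cytochrome c1, fell by 1.68 on the log2 scale (adjusted p = 0.0264). The fixed list of nuclear-encoded oxidative phosphorylation genes, to which Cox5a belongs, differed by -0.00946 in mean log2 CPM between record set 2 and record set 1 and by 0.13 between record set 2 and female A, and was not tested between record sets. Saraf, a regulator of store-operated calcium entry, fell by 1.87 and Ddost, a subunit of the oligosaccharyltransferase, by 1.83 (both adjusted p = 0.0175). The calcium-binding protein gene Calb1 fell by 2.00 (adjusted p = 0.032), and Mrgprd fell by 0.84 (adjusted p = 0.0431), standing at 295 to 369 CPM in record set 1 and at 184 and 197 CPM in record set 2. Genes higher in record set 2 included Kif26a, an atypical kinesin gene linked to Ret signalling in enteric neurons, at 7.42 and 8.27 CPM against 0.602 to 0.959 CPM (log2 change 3.29, standard error 0.31, adjusted p = 0.0144), and Spry2 (log2 change 2.65, adjusted p = 0.044). The volume-regulated anion channel gene Lrrc8a rose by 1.43, the sodium channel subunit gene Scn2b by 1.13 and the mitochondrial calcium uniporter gene Mcu by 1.59, with adjusted p of 0.0175, 0.0193 and 0.0193. The exons of Lrrc8a overlap another annotated gene over 2853 bp and those of Cox5a over 269 bp. The immediate early gene Fos rose (adjusted p = 0.0193), at 685 and 500.2 CPM in record set 2 and 179.6 to 237.6 CPM in the other libraries of that fit, while male A, left out of it, had 484 CPM. That fit called 199 of 15335 genes, 101 higher and 98 lower in record set 2. Among the 3 female libraries alone edgeR called 115 of 13856 genes, 62 higher and 53 lower, of which 82 were shared with the 199. Both fits hold the same 3 female libraries, so the overlap is not independent, and female A is a single library assumed to vary like the others. In the comparison planned before the data were examined, over the 6 libraries with sex as a term, edgeR called 0 of 14958 genes, with 483 at an unadjusted p under 0.05 (208 higher and 275 lower). Limma voom called 0 and DESeq2 called 13 (5 higher and 8 lower). With male A kept and no sex term, also chosen after the data were seen, 3 genes were called. Record set 2 held only females of 1 embryo each, so record set and pool size cannot be told apart here.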

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

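Of the tests in this part, the comparison of erythroid markers in male A was chosen only after the result was seen, while the GC and length test was fixed before its result, although trends with GC content and length had been seen. In 31 quantities per library, the gap between the most extreme library and its nearest neighbour was divided by the whole range of the 6 libraries and compared with Dixon's 95% critical value for 6 samples, which chance passes in about 1 of 20. Groups of 3 were not tested. A library stood apart in 7 quantities, and in 5 of them it was male A. Male A was high for satellite glia and Schwann cell markers (0.8317; mean log2 CPM 6.91 against 5.42 to 5.67), fibroblast and meningeal markers (0.7783; 5.95 against 3.80 to 4.28) and cell cycle genes (0.8493; 4.87 against 2.93 to 3.22). It was low for axon guidance genes (0.7011; 3.73 against 4.19 to 4.39) and for steroid hormone receptors and enzymes (0.6649; 3.30 against 3.77 to 4.00). Male C was low for peptidergic nociceptor markers, by a margin only in the last of 4 decimals (0.6252; 6.04 against 6.15 to 6.21). Male C also had the highest total count, 29330101 against 17861500 to 21734364 (0.6623).

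The high glia, fibroblast and cell cycle genes of male A were set against technical explanations, and no biological explanation was tested because the labels give no group that male A alone belongs to. Male A differed from the others in a trend with GC content, with a median log2 difference from -0.485 in the lowest of 5 GC bins to 0.456 in the highest. Of 10000 random lists matched on GC content, length and level 0 reached the median of 1.69 of the 48 list members, which argues against these trends as the whole cause. The lists had been picked because they stood high in male A. Matched genes were drawn independently, whereas members of these lists vary together (estimated correlations 0.292 for glia, 0.617 for fibroblasts and 0.75 for cell cycle genes). The count of 0 therefore overstates the strength of this evidence. A lower share of sorted neurons with every other cell type raised alike would raise the erythroid list too, but that list differed by -1.07 on the log2 scale. The SD of the other libraries was 0.722 and male C was equally low (1.26 against 1.29 in male A), so this list does not set male A apart. It bears only on a rise of every cell type alike and cannot decide whether the share of neurons was lower. Pan-sensory genes were lower (-0.41), and the glia (1.41), fibroblast (1.98), endothelial (1.85), macrophage (1.22), sympathetic and enteric (1.94) and cell cycle lists (1.73) higher. A larger share of particular cell types, such as dividing glia or fibroblasts, may also account for the high glia, fibroblast and cell cycle genes. That was not tested, although the sort would remove cells without EGFP, with Apoe at 964.9 CPM and Col3a1 at 847.8 CPM in male A.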

How the results depend on the processing

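The fits without male A and male C and those of record sets without a sex term were chosen only after the data were seen. Between the sexes 4 genes were called, all on the Y chromosome, and the count was also 4 with RLE, upper quartile, the 1 CPM filter, robust dispersion or pooled embryos as a term. It was 14 without a low-count filter (8 autosomal), 13 with DESeq2 (8 autosomal), 1 with limma voom, and 0 to 5 over the fits leaving out 1 library each (0 to 1 autosomal). With the replicate block it was 77 (65 autosomal), with 1 residual degree of freedom; the letters share only a name in 2 pairs, whose residual correlations were -0.0777 (A) and 0.0521 (C), so lost or gained calls are not read as weaker or stronger effects. Of gene lists, 10 were called, against 4 to 11 leaving out 1 library each (4 without male A), 3 without male A and male C, 0 with an estimated correlation, and 1 by fry in 1 direction and 1 in either direction. With the 1 CPM filter the macrophage list had too few members for a test. The record set comparison, 0 with sex as a term, gave 3 without a low-count filter, 13 with DESeq2, 115 in females only, 3 without a sex term and 199 without a sex term and without male A; leaving out 1 library gave 0, and without female A it could not be fitted. The fits without a library or with 1 sex hold fewer libraries. Between the sexes, record set as a term or record set 1 only sets female A alone against the males, so counts of these fits are not given. Otherwise the cause of the changed counts was not tested. Of 1545 values for 86 named genes, 0 reversed a call, 6 gained and 17 lost one, the lost ones all of the 4 Y genes, and 45 genes that were not called changed sign in at least 1 setting. On the TPM scale, which divides by gene length, Gfra3 averaged 621.5, Ret 69.4, Gfra2 64.8 and Gfra1 17.5, in the order of their CPM levels. Depth limits levels under 0.102 to 0.168 CPM.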

Other observations

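In this part the Xist tests, the shared calls within the females, the place of the males in genes called within the females and the counts over other splits were chosen only after the results were seen. Some genes of the sympathetic and enteric list were highest in male A. Dbh, which encodes dopamine beta-hydroxylase, was at 18.3 CPM in male A and 4.41 CPM in female C and at 0.111 to 1.46 CPM in the other 4 libraries. The transcription factor gene Gata3 was at 3.66 CPM in male A, 2.20 CPM in female C and 0.388 to 0.720 CPM elsewhere. Ddc, the next enzyme of catecholamine synthesis after Th, was at 4.81 CPM in male A and 2.20 CPM in female C, and the noradrenaline transporter gene Slc6a2 at 6.54 CPM in male A and at most 1.19 CPM elsewhere. The monoamine transporter gene Slc18a2 of the same list did not follow this order, at 37.97 CPM in male A, 104.5 CPM in female C and 19.86 to 69.78 CPM elsewhere. These genes were chosen after their values were seen and were not tested.

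Counts of mitochondrially encoded mRNAs were uneven among genes. Over the 6 libraries mt-Cytb had 752699 counts, mt-Nd1 490098 and mt-Co1 432049, whereas mt-Co2 had 1, mt-Atp6 3, mt-Co3 4, mt-Nd3 2, and mt-Nd4l and mt-Atp8 0. The mitochondrial list of the sex comparison therefore rests on 7 of 13 genes.

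Xist in the library labelled male C was 40.2% of the female mean. A female library under a male label is argued against by the 4 Y-linked genes, the lowest of which had 9.73 CPM in male C, against at most 0.401 CPM in a female library. Reads passing between libraries at the rate seen elsewhere are argued against by the same 40.2%, since Xist was at 0.285% and 0.393% of the female mean in male A and male D and females held at most 0.7% of the male level of a Y-linked gene. RNA of female cells in the pool, which held embryos of 2 mothers, may account for it and stays open: the Y-linked genes of male C were -0.856 on the log2 scale from the mean of male A and male D, near the -0.742 that the Xist share would give, but male A and male D themselves differ by 1.1.

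The genes that set female B and female C apart were weighed over the 199 calls made without male A. Trends with GC content and length are argued against as the cause, since 195 of the calls stayed after a correction of each library for both, which called 455 genes in all (median absolute log2 change 1.14 before and 1.13 after), and so are reads shared with near-identical copies, found in 10.2% of the genes called lower and 11.3% of other genes. Sex stays open: the 191 calls also tested within the females had a median absolute log2 change of 1.11 there against 1.13 in the fit without male A, and 82 were called, but both fits share these libraries and that within the females rests on female A alone in an arm, and among 5 autosomal genes called between females B and C and males C and D female A had a median position of 0.259 from males (0) to females B and C (1), with a standard error of 0.145. Female A standing apart alone is argued against as the cause of the 115 calls within the females. On a scale from females B and C (0) to female A (1), the males, which had no part in choosing these genes, had median positions of 1.14 (male A, standard error 0.0797), 1.03 (male C, 0.0501) and 0.883 (male D, 0.0138). These standard errors, like the 0.145 above, come from resampling genes and do not measure the spread between libraries. Female A also had the highest mean correlation with the other libraries (0.9699) and the fewest genes over 2-fold below all others (23). It had 5 genes over 2-fold above all others, where male C had 1. Record set, pool size, parents and any batch cannot be told apart here.

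The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4 genes and the other splits at most 0, so that 1 of 10 splits had as many. For autosomal genes the real split called 0 and the other splits at most 0, so that 10 of 10 had as many. For gene lists the real split called 10 and another called 13, and 3 of 10 splits had as many. The splits that called more were male A and male D with female C (13) and with female B (11).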
